A study of Arabidopsis thaliana with 17 samples.

How the data were processed

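Gene expression was measured in 3-week-old soil-grown Arabidopsis thaliana plants on 17 Affymetrix ATH1 arrays. Plants received 0.5 mM salicylic acid (SA), a hormone of plant immunity, or water, and were sampled 16 hours later. Every plant carried the npr1 and sni1 mutations (called the double). NPR1 is a co-activator of SA-responsive genes and SNI1 a repressor of them. The brca2a triple and the ssn2 triple carried 1 further mutation each. BRCA2A takes part in homologous recombination, and the name SSN2 stands for suppressor of sni1. Per the labels' protocols, total RNA was extracted with a Qiagen RNeasy Plant Mini kit and biotin-labelled with the Ambion MessageAmp Premier kit. Replicates came from independent biological experiments, per the series design. The double and the brca2a triple had 3 arrays per treatment. The ssn2 triple had 3 water arrays and 2 SA arrays. The treatment text of the ssn2 samples names brca2a, while their titles, genotype entries and the series design name ssn2. One of the ssn2 water samples carries its treatment under a label meant for a pathogen. The titles and genotype entries were followed.

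The authors deposited linear probe set intensities in 2 tables, 1 with the 12 arrays of the double and the brca2a triple and 1 with the 5 ssn2 arrays. PLIER is named in the submitters' processing notes, and its version and settings are not given in the sources used here. Intensities lay between 3.92 and 14773 and never fell below 0. Array medians lay between 57.2 and 61.9, and within a table the medians of log2 intensity spanned 0.0886 (12 arrays) and 0.0648 (5 arrays), so the arrays had been normalized to each other within a table. The upper ends of the 2 tables differed, so they were taken as normalized separately, and all tests were made within 1 table. The deposited series value table holds log2 values of the same arrays. For the 12 arrays these were log2 intensity minus each probe set's median over the 12, to within 1.98e-06. For the 5 ssn2 arrays they were log2 intensity minus a constant per probe set whose origin stayed unknown. Its array medians lay between -0.0216 and 0.0287, and its direction followed log2 intensity on every array. It served only as an alternative source. Arrays have no read depth; their number limits the precision.

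Intensities were transformed as log2(intensity + 16), which understates changes of dim probe sets. No filter on dim probe sets was applied. Of 22810 probe sets, 64 controls were left out and 22746 were tested. The platform table listed 13513 probe sets with 1 gene and 503 with several; 8730 were not listed in it and stay unnamed here. Of the 13513, 13436 matched a locus tag of the RefSeq annotation of assembly TAIR10.1, which gave 13286 loci. Symbols come from that annotation, and loci without a symbol are named by locus tag. No probe set with several genes was used to name a gene. The named genes are therefore not always the largest changes. Among unlisted probe sets, 1 had a log2 fold change of -6.02 with SA in the ssn2 triple, larger than that of any gene named here. Another had -1.27 in the brca2a triple against the double in water, larger in size than that of any named gene past the threshold in that comparison.

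Group means were fitted with limma's lmFit and eBayes at default settings (limma 3.58.1 in R 4.3.3), with 1 fit for the 12 arrays and 1 for the 5. Contrasts were SA against water in each genotype, the difference between the SA effects of the brca2a triple and the double (interaction), and the brca2a triple against the double in water and after SA. All adjusted p-values are Benjamini-Hochberg values of limma over all 22746 probe sets of a contrast unless stated otherwise, the threshold was 0.05, and tests were two-sided. Errors of log2 fold changes are standard errors of the fit. The difference in SA effect between the ssn2 triple and the double was not tested because the tables were normalized separately. No array of the double was made with the ssn2 arrays, so genotype and experiment cannot be told apart in any level set across the tables. P-values rest on replicates that the labels call independent experiments.

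Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, on the brightest probe set of each gene, with Benjamini-Hochberg adjustment over the lists of a contrast. The same test with an estimated correlation is given beside each call. The comparisons, the lists, the rule for naming genes and the alternatives, unless stated otherwise, were set before the data were examined. Of the 21 lists with 321 genes, 38 genes had a one-gene probe set, and 8 lists had the 3 members needed for a test. Genes are called measured here if they had a one-gene probe set, and the 8730 unlisted probe sets may hold further members. Because so few members could be identified, 40 gene families defined by symbol stem (at least 6 loci each, plastid-encoded genes included) and 4 further lists were added after the data were seen. The 4 hold genes that respond to iron deficiency (6 members), rapidly to stress (27), to daylight (8) and to darkness (7). A list of 4 glucosinolate genes and 3 candidates for the dark list were dropped when the lists were written. The fall of 1 of these candidates, AT1G55960, in the ssn2 triple had been seen by then and was a reason to drop it. All were later put back in a further test.

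The genes named for a comparison were the 8 that rose and the 8 that fell most among one-gene probe sets past the threshold, with every array of 1 group above every array of the other (which chance gives to 10% of genes for 3 arrays against 3). For the interaction the difference of group means alone was used. Members of the fixed lists were added, at most 2 rising and 2 falling past the threshold, or else the member with the smallest p as a value. PR1, PR2, PR5 and the genes NPR1, SNI1, BRCA2A, SSN2 and RAD51D were to be reported too. None of these 8 had a one-gene probe set in the table, so they were not analysed here and the genotype labels were not checked by expression.

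RNA quality was judged from the log2 ratio of 3-prime to 5-prime control probe sets of actin and GAPDH (2 designs each), with exact two-sided permutation tests. The code was tested on simulated data drawn on the real arrays' means and spreads, with 200 of 22746 probe sets changed. It recovered 82.1% of 1.5-fold and 100% of 2-fold changes for SA in the double, 85.1% and 97% for SA in the brca2a triple, and 59.7% and 92.5% for the interaction. For the brca2a triple against the double it recovered 92.5% and 97% in water and 85.1% and 98.5% after SA, and 95.5% and 100% for SA in the ssn2 triple. Unchanged probe sets made up 7%, 2.08%, 3.45%, 1.53%, 2.59% and 5.74% of the simulated calls (SA in the double, SA in the brca2a triple, interaction, water, after SA, SA in the ssn2 triple), so for SA in the double and the ssn2 triple the share was above 5%. Each simulated probe set had the same spread on all arrays of a fit, and no array lay apart. In the real data water replicate 2 of the double did, so these shares may not hold for the real fits. Among 200 unchanged simulated gene lists, 4 passed an unadjusted 0.05, and a list raised 1.5-fold passed. The simulated genes were drawn independently of each other, so these lists cannot show how the list test behaves on genes that vary together. Alternatives tried were other offsets (1 and 64), quantile normalization, median centring, a filter on the dimmest 30% of probe sets, a trended robust variance, the groups of a comparison alone, the replicate number as a block, an adjusted p of 0.1, a 2-fold minimum, the series value table, single-gene probe sets, and leaving out each array. Without an ssn2 SA array 1 SA array is left, which is assumed to vary like the water arrays. Array weights, and leaving out each array for the families and further lists and the return of dropped candidates, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.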

Results

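Expression was measured on 17 arrays in 6 groups: the double (npr1 sni1), the brca2a triple (npr1 sni1 brca2a) and the ssn2 triple (npr1 sni1 ssn2), each after water or SA. Each group had 3 arrays except the ssn2 triple after SA, which had 2. In the 12 arrays of the double and the brca2a triple, the first principal component held 44.9% of the variance and the second 20.5%. The 3 SA arrays of the double lay together at 26 to 26.4 on the first component, those of the brca2a triple at 3.33 to 4.08, and the brca2a triple in water between -20.9 and -19.7. Among the water arrays of the double, replicates 1 and 3 lay at -19.9 and -20.9, and replicate 2 lay apart from them at 11.9 on the first and 28.8 on the second component. Its correlation with replicates 1 and 3 across probe sets was 0.981 and 0.980, against 0.997 between those. It stays in every fit of these 12 arrays, and their counts are also given without it, as part of leaving out each array in turn. The ratios of 3-prime to 5-prime control probe sets differed between groups by -0.21 to 0.15 (log2, 3 arrays against 3 or 2). These group sizes allow no exact permutation p below 0.1, so the tests cannot show that RNA quality was alike; 1 GAPDH ratio, for SA in the ssn2 triple, differed by 0.12 and reached that smallest p (0.1).

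**Figure D1:**
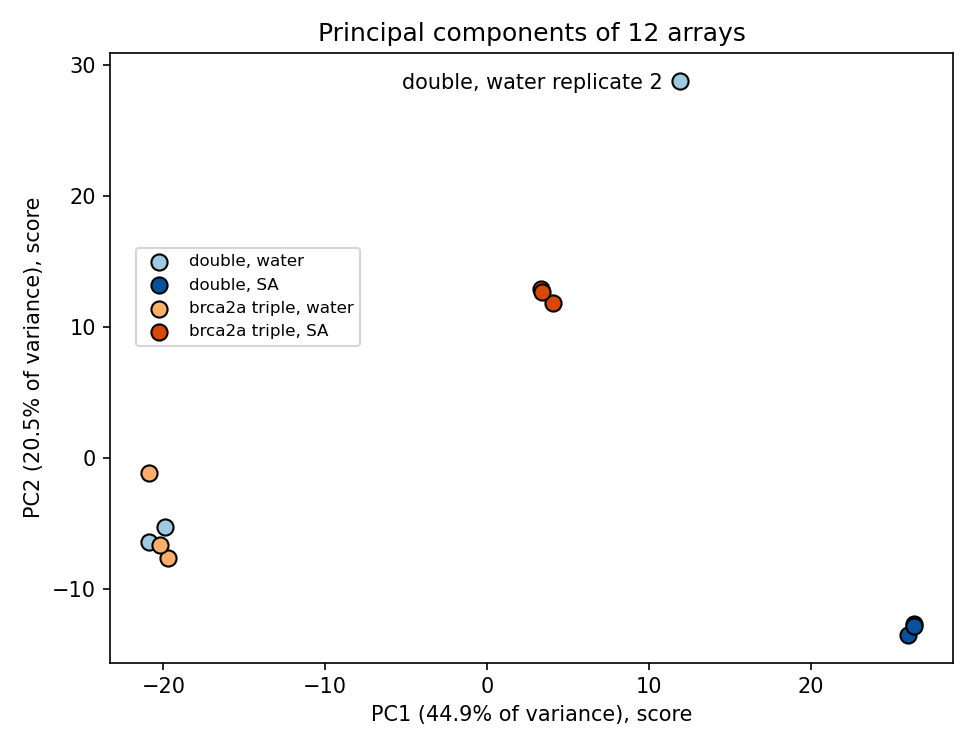
Scores of the 12 arrays of the double and the brca2a triple on the first (x axis, 44.9% of variance) and second (y axis, 20.5% of variance) principal component of log2 values, 1 point per array, coloured by group. Water replicate 2 of the double lies at 11.9 and 28.8, apart from replicates 1 and 3 of its group.

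The first comparison asked what SA did in npr1 sni1 plants. SA raised AT5G52760 10.6-fold, or 3.40 ± 0.15 on the log2 scale (standard error, 3 arrays against 3, adjusted p = 6.2e-07). AT5G55450 rose by 3.16 ± 0.22 (adjusted p = 1.2e-05), CML38, which encodes a calmodulin-like protein, by 2.89 ± 0.19 (6.5e-06), and AT5G03350 by 2.83 ± 0.09 (1.2e-07). AT4G29780, AT1G15010, AT5G52750 and AT3G01830 rose by 2.70 to 2.82. By the rule for naming genes, every SA array lay above every water array in each of these genes. Of the 2 measured SA response genes, GRX480, a glutaredoxin gene induced by SA, rose by 2.46 ± 0.17 (adjusted p = 9.7e-06) and WRKY53, a transcription factor gene, by 1.93 ± 0.09 (6.2e-07). SAG101, which encodes a partner of the immune regulator EDS1, rose by 0.50 ± 0.06 (adjusted p = 7e-04).

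All 3 measured genes of the endoplasmic reticulum (ER) secretory pathway rose in the double after SA, and all 3 also passed when adjusted over the list alone. They were ATERDJ3B, which encodes an ER co-chaperone (0.93 ± 0.06, 3 arrays against 3, adjusted p = 7.1e-06), AT5G07340 (0.63 ± 0.08, 0.00057) and the calreticulin gene CRT1b (0.36 ± 0.09, 0.029). The list passed camera (adjusted p = 2e-06 over 8 lists; adjusted p = 0.024 with an estimated correlation). Without double, SA replicate 2 the adjusted p of CRT1b was 0.11, and it was 0.095, 0.07 and 0.073 without double, water replicate 1 and SA replicates 1 and 3. Of the 3 measured jasmonate genes, the defensin gene PDF1.2b fell by 0.42 ± 0.07 (adjusted p = 0.0054); 2 fell adjusted over the list alone, and the list had adjusted p = 0.086 (0.028 without double, water replicate 3). AUR1, an Aurora kinase gene of the cell cycle list, rose by 0.37 ± 0.07 (adjusted p = 0.0066), and the alkenal reductase gene AER of the detoxification list fell by 0.42 ± 0.08 (0.0071). The detoxification, recombination and repair, photosynthesis, cold and abscisic acid, anthocyanin and reference gene lists did not pass (adjusted p = 0.71, 0.71, 0.82, 0.71, 0.095 and 0.87); without brca2a triple, SA replicate 2, which enters only through the shared spread, the anthocyanin list had 0.026, downward.

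Fewer genes fell strongly in the double. AT3G15720 fell, with a log2 fold change of -1.24 ± 0.14 (3 arrays against 3, adjusted p = 0.00036), and so did AT1G20070 with -1.09 ± 0.16 (0.002), AT2G28200 with -1.0 ± 0.16 (0.0037; 0.059 with the 2 groups fitted alone) and AT1G49470 with -0.95 ± 0.10 (0.00027). AT1G47400 had a log2 fold change of -1.36 ± 0.30 (adjusted p = 0.021) and BHLH101, a transcription factor gene of the iron deficiency response, -1.16 ± 0.30 (0.041). AT3G44450 and AT3G52740 had -1.18 ± 0.31 (0.046) and -0.89 ± 0.24 (0.048). The calls of these 4 genes ended when single arrays were left out: any of the 3 SA arrays of the double for AT1G47400 (adjusted p up to 0.079), 8 of 12 arrays for BHLH101 (up to 0.12; all but the 3 water arrays of the double and brca2a triple, water replicate 2), and 11 of 12 for AT3G44450 and AT3G52740 (up to 0.17 and 0.16), double, water replicate 2 being the exception.

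In all, 1700 of 22746 probe sets changed with SA in the double, 1123 higher and 577 lower, and 309 of them at least 2-fold (298 higher, 11 lower). The 1700 included 860 named loci. The share that was higher depended on the scaling, at 66.1% as deposited and 50.3% (1027 higher, 1016 lower) with each array centred on its median. Without double, water replicate 2 the count was 4464 (2123 higher, 2341 lower), of which 1672 were among the 1700 and in the same direction; without double, SA replicates 1, 2 and 3 it was 1090, 1114 and 1097.

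The second comparison asked what SA did when BRCA2A was also mutated. ARR15, a response regulator gene of cytokinin signalling, rose by 1.34 ± 0.13 (3 arrays against 3, adjusted p = 0.002), AT4G17470 by 1.47 ± 0.20 (0.0062), AT1G35710 by 1.37 ± 0.17 (0.0047), AT3G04210 by 1.28 ± 0.18 (0.0066) and AT4G11900 by 1.23 ± 0.18 (0.0072). AT3G62950, AT2G16660 and the cytochrome P450 gene CYP71B23 had log2 fold changes of 1.66, 1.52 and 1.25 (adjusted p = 0.033, 0.018 and 0.023). Among genes that fell, AT1G47400 had -1.74 ± 0.30 (adjusted p = 0.013), AT1G25550 -1.14 ± 0.18 (0.0097), AT5G05250 -1.11 ± 0.16 (0.0074) and AT3G15720 -0.80 ± 0.14 (0.015). BHLH101, AT5G51440, AT3G46600 and AT2G19310 had -1.22, -1.14, -0.88 and -0.85 (adjusted p = 0.045, 0.029, 0.022 and 0.039). The SA response genes GRX480 and WRKY53 had log2 fold changes of 0.11 ± 0.17 and 0.01 ± 0.09 (adjusted p = 0.76 and 0.97), and SAG101 0.15 ± 0.06 (0.2). Several calls ended without any 1 of the 6 brca2a triple arrays: those of AT3G62950 (adjusted p up to 0.11), CYP71B23 (up to 0.077), AT5G51440 (up to 0.094), AT3G46600 (up to 0.078), BHLH101 (up to 0.14) and AT2G19310 (up to 0.11). Those of AT3G62950, BHLH101 and AT2G19310 also ended without any 1 SA array of the double, that of AT2G16660 without brca2a triple, water replicate 2 or 3 (0.056 and 0.052), that of AT3G15720 without SA replicate 2 (0.056) and that of AT1G47400 without SA replicate 3 (0.052). Across the alternatives the lowest adjusted p of AT3G62950, CYP71B23, AT5G51440, AT3G46600, BHLH101 and AT2G19310 was 1.3e-05, 6.3e-05, 1.4e-05, 1.3e-05, 0.00093 and 3.2e-05. The shared spread takes in the water arrays of the double, where the SD of each of these genes was highest. For AT3G62950 it was 0.98 there, against 0.26 (water) and 0.04 (SA) in the brca2a triple.

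The ER secretory list passed in the brca2a triple too (adjusted p = 0.0023), but with an estimated correlation it had adjusted p = 0.15. ATERDJ3B rose by 0.32 ± 0.06 (3 arrays against 3, adjusted p = 0.02; 0.072 and 0.061 without brca2a triple, SA replicates 1 and 3), and adjusted over the list alone all 3 members rose. AT5G07340 and CRT1b had 0.26 and 0.24 (adjusted p = 0.09 and 0.14). In the detoxification list AER had -0.37 ± 0.08 (adjusted p = 0.027; up to 0.092 without brca2a triple, water replicates 1 or 3 or SA replicates 1 or 3), and in the cell cycle list PRL, which encodes a subunit of the replicative helicase, had -0.26 ± 0.06 (0.039; up to 0.12 without any 1 brca2a triple array, or without double, SA replicates 1 or 3). The other 7 testable lists had adjusted p between 0.31 and 0.68, and without brca2a triple, SA replicate 2 the cold and abscisic acid list had 0.0015, downward.

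SA changed 1057 probe sets in the brca2a triple, 593 higher and 464 lower, including 526 named loci; 75 changed at least 2-fold. The share that was higher was 56.1% as deposited and 45.5% (542 higher, 649 lower) after median centring. Without double, water replicate 2, which enters this comparison only through the shared estimate of the spread, the count was 3495. It was 474, 653 and 457 without brca2a triple, water replicates 1, 2 and 3, and 477, 410 and 379 without SA replicates 1, 2 and 3. Across all probe sets the SA effects of the double and the brca2a triple, which share no array, correlated at Pearson r = 0.404 (Spearman rho = 0.352), across genes that are not independent replicates. This r was 0.567 without double, water replicate 2 and 0.287 and 0.278 without its replicates 1 and 3. Both genotypes had 317 probe sets higher and 100 lower in common, where independent lists would share 29.3 and 11.8. The 2 lists are not independent, because they use the same estimate of the spread of each probe set. How much of the excess comes from that was not tested. Among the 11373 brighter probe sets 258 and 91 were shared, against 34 and 16.7.

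**Figure D2:**
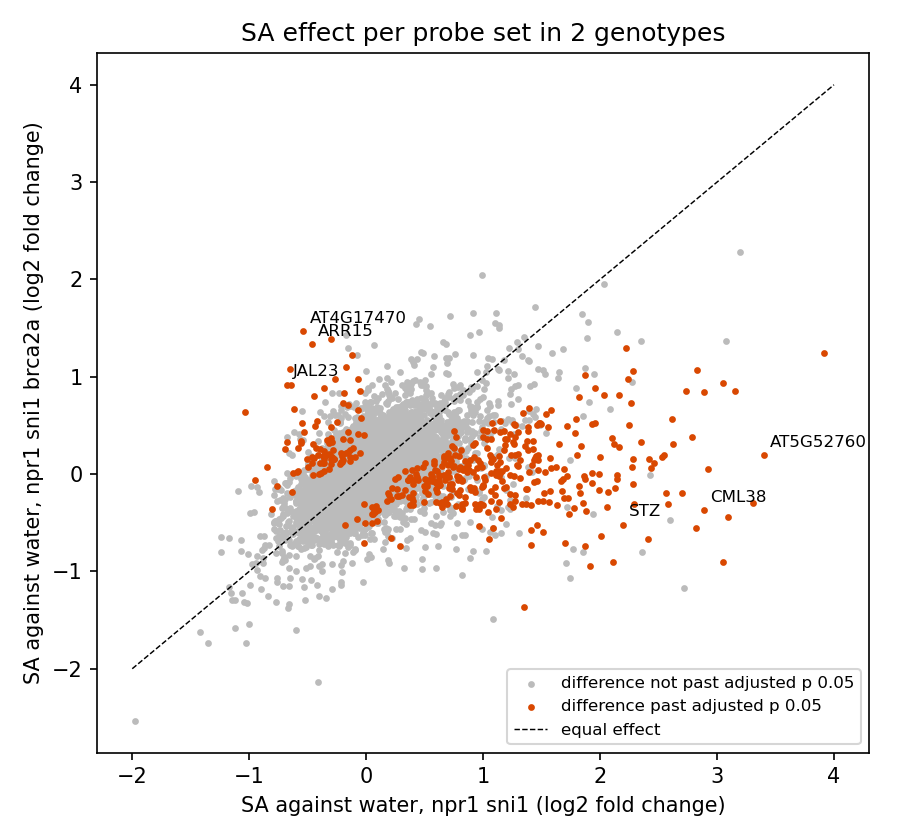
Log2 fold change of SA against water in npr1 sni1 (x axis) and in npr1 sni1 brca2a (y axis), 1 point per probe set, with the 442 probe sets whose SA effect differed between the genotypes (adjusted p under 0.05) in orange and a dashed line where both effects are equal. AT5G52760, CML38 and STZ lie far to the right near 0 on the y axis, and ARR15, JAL23 and AT4G17470 lie above 0 on the y axis and below 0 on the x axis.

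The third comparison tested whether the brca2a mutation changed the SA effect itself. The SA effect on AT4G29780 was lower in the brca2a triple than in the double by 3.38 ± 0.34 on the log2 scale (-3.38, 12 arrays, adjusted p = 0.00051), that on CML38 had a difference of -3.26 ± 0.27 (0.00012), and that on AT5G52760 one of -3.20 ± 0.22 (4e-05). AT3G01830 (-2.89), the zinc finger transcription factor gene STZ (-2.71), AT4G27654 (-2.60) and AT1G15010 (-2.40) followed. In the double these 7 genes rose by 2.19 to 3.40, and in the brca2a triple their SA effects lay between -0.56 and 0.39, with none past the threshold. They were named for the lowest differences, so effects near 0 partly follow from that choice. Some other genes that rose most in the double kept part of their SA effect. In the brca2a triple AT5G03350 rose by 1.07 ± 0.09 (adjusted p = 0.0013) and AT5G52750 by 0.85 ± 0.16 (0.017). AT5G55450 had 0.85 ± 0.22, which did not pass (0.061). The differences of these genes, in this order, were -1.76, -1.88 and -2.30 (adjusted p = 4.6e-05, 0.0013 and 0.0035). The SA response genes also differed: GRX480 by -2.35 ± 0.24 (adjusted p = 0.00051) and WRKY53 by -1.92 ± 0.12 (3.1e-05). SAG101 had a difference of -0.35 ± 0.09 that did not pass (adjusted p = 0.095). In the other direction, AT4G17470 had a difference of 2.0 ± 0.29 (adjusted p = 0.0044), ARR15 of 1.80 ± 0.19 (0.00057) and the jacalin-related lectin gene JAL23 of 1.60 ± 0.14 (0.00016). JAL23 fell by 0.68 ± 0.10 in the double and rose by 0.92 ± 0.10 in the brca2a triple. AT2G43530 and AT5G47330 followed with 1.05 (0.0075) and 0.92 (0.014). AT2G27080 (-2.61, adjusted p = 0.037), AT1G30250 (1.07, 0.017), AT2G43550 (1.01, 0.017) and AT5G44050 (0.96, 0.027) lost their calls without single arrays: 9 of 12 for AT2G27080 (up to 0.1, all but the 3 water arrays of the double), 7 for AT5G44050 (up to 0.079: double, water replicate 3 and SA replicates 1 and 3, brca2a triple, water replicates 1 and 3 and SA replicates 1 and 2), brca2a triple, water replicate 1 and SA replicates 1 and 3 for AT1G30250 (up to 0.056), and water replicate 3 and SA replicate 3 for AT2G43550 (0.053 each).

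**Figure D3:**
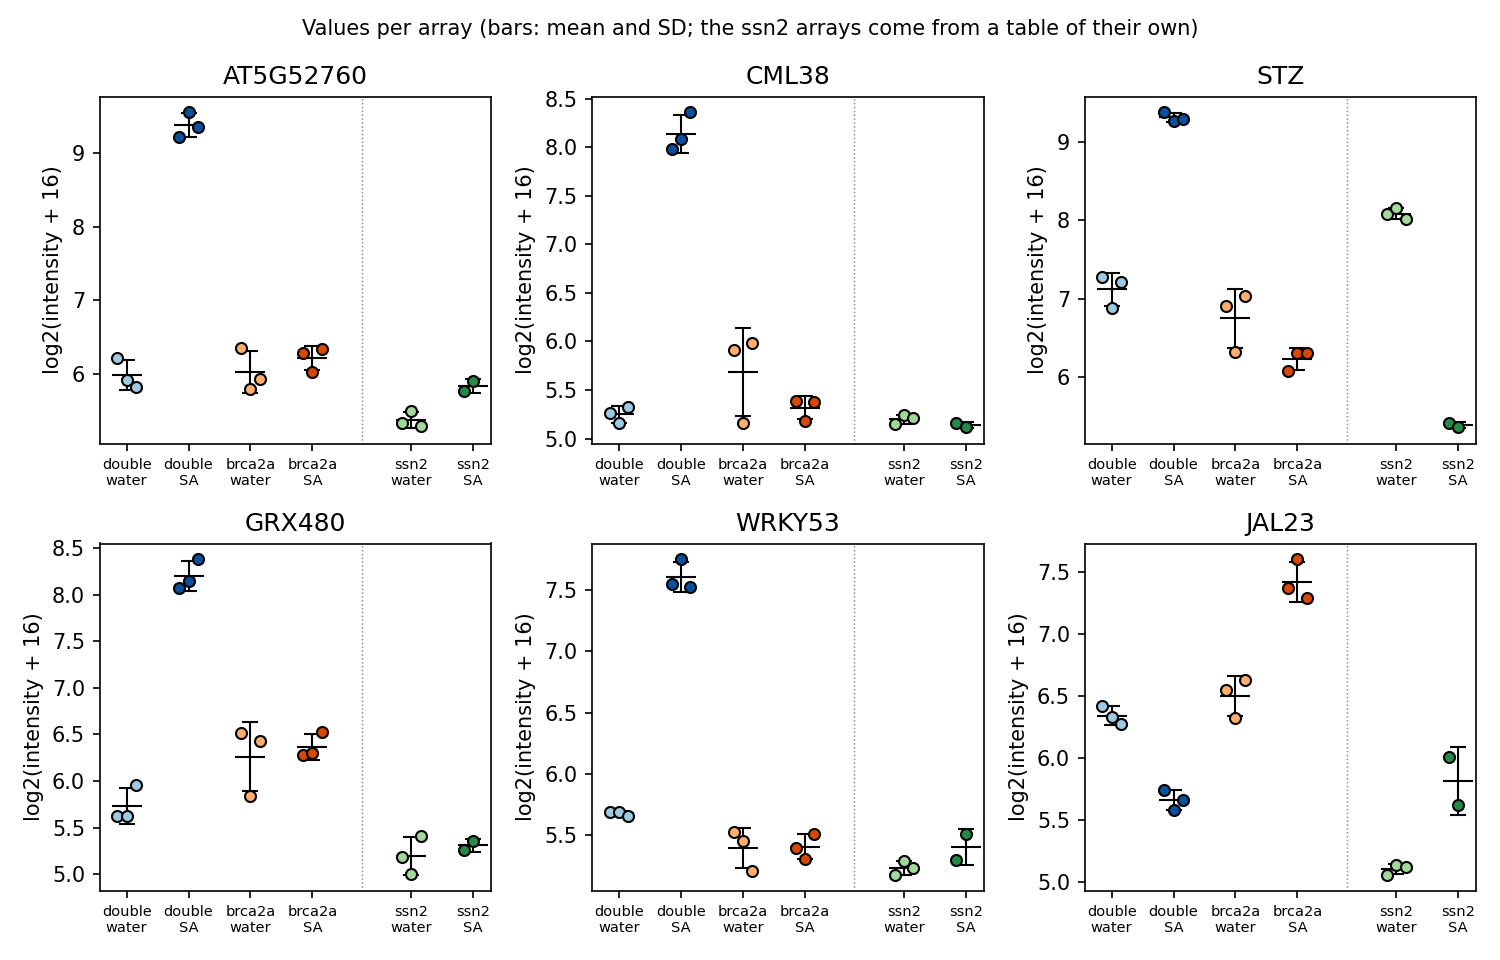
Values of 6 genes on each array as log2(intensity + 16) (y axis), 1 point per array, grouped by genotype and treatment (x axis), with bars for the group mean and SD; the ssn2 arrays, right of the dotted line, were normalized in a table of their own. In the first 5 panels the 3 SA arrays of the double lie above all other arrays, and in the JAL23 panel the 3 SA arrays of the brca2a triple do.

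For 442 probe sets the SA effect differed between the genotypes, more positive in the brca2a triple for 91 and more negative for 351. They included 209 named loci, and 195 differed at least 2-fold (17 and 178). Without double, water replicate 2 the count was 1065 (413 and 652), all 442 among them in the same direction. The ER secretory list had a lower SA effect in the brca2a triple (adjusted p = 0.0067; adjusted p = 0.21 with an estimated correlation): ATERDJ3B passed with -0.61 ± 0.09 (adjusted p = 0.004), AT5G07340 (-0.37, 0.16) and CRT1b (-0.12, 0.77) did not, and 2 passed adjusted over the list alone. The other 7 testable lists had adjusted p between 0.36 and 0.89, and without brca2a triple, SA replicate 2 the cold and abscisic acid list had 0.00025, downward. Probe sets that at least doubled in 2 replicate numbers of the double were also measured in the remaining one. Over 318, 378 and 323 such probe sets (held-out replicates 1, 2 and 3) the median log2 SA effect was 1.44, 1.04 and 1.40 in the held-out pair of the double and 0.154, 0.403 and 0.144 in the brca2a triple.

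The fourth comparison asked what the brca2a mutation changed without SA. COR15B, a cold-regulated gene, was higher in the brca2a triple in water by 1.15 ± 0.11 (3 arrays against 3, adjusted p = 0.0082). Its call ended without double, water replicate 3 (adjusted p = 0.052) and with the 2 groups fitted alone (0.14). The other named genes past the threshold were AT5G03350 (0.64, adjusted p = 0.037), AT3G56480 (0.36, 0.037), AT1G77600 (0.36, 0.036), AT2G30620 (-0.45, 0.037) and AT4G30310 (-0.32, 0.036). Each of these 5 calls ended without 9 to 11 of the 12 arrays taken singly (adjusted p up to 0.15) and with the 2 groups fitted alone (0.46 each), and all 5 held without double, water replicate 2. The cold and abscisic acid list was higher (adjusted p = 0.00014; adjusted p = 0.23 with an estimated correlation), with COR15A at 2.01 ± 0.41 (0.17) and COR47 at 0.32 ± 0.20 (0.57), and COR15B and COR15A passed adjusted over the list alone. GRX480 and WRKY53 had 0.52 and -0.28 (adjusted p = 0.31 and 0.3). The other 7 testable lists had adjusted p between 0.3 and 0.89. Only 17 probe sets passed, 10 higher and 7 lower (10 and 13 after median centring, 8 and 11 after quantile normalization), where 2622 had an unadjusted p under 0.05. The count was 107 without double, water replicate 2, and 6 and 1 without its replicates 1 and 3. It was 3, 3 and 4 without double, SA replicates 1, 2 and 3, 7 and 4 without brca2a triple, water replicates 1 and 3, and 4 and 3 without brca2a triple, SA replicates 1 and 3.

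The fifth comparison set the brca2a triple against the double after SA. AT4G29780 was lower in the brca2a triple by 3.36 ± 0.24 (-3.36, 3 arrays against 3, adjusted p = 1.8e-05), AT5G52760 had -3.17 ± 0.15 (1.7e-06), STZ -3.09 ± 0.17 (2.7e-06), CML38 -2.82 ± 0.19 (1.2e-05) and the ubiquitin ligase gene PUB23 -2.36 ± 0.15 (7.7e-06). AT3G01830, AT4G27654 and AT5G55450 had -2.60, -2.44 and -2.38. The SA response genes WRKY53 and GRX480 were lower as well, with -2.21 ± 0.09 (adjusted p = 3.7e-07) and -1.83 ± 0.17 (9.6e-05), and so was SAG101, with -0.42 ± 0.06 (0.0033). AT4G17470 was higher by 2.67 ± 0.20 (adjusted p = 2.6e-05), AT2G43550 by 1.79 ± 0.13 (1.8e-05), JAL23 by 1.76 ± 0.10 (3e-06) and AT3G28220 by 1.71 ± 0.20 (6e-04). BCAT4, an aminotransferase gene of methionine-derived glucosinolate synthesis, was higher by 1.29 ± 0.11 (5.3e-05). AT1G52000, AT5G44050 and ARR15 were higher by 1.41, 1.19 and 1.17.

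Among the lists, the ER secretory genes were lower in the brca2a triple after SA (adjusted p = 0.00022; adjusted p = 0.074 with an estimated correlation), with ATERDJ3B at -0.58 ± 0.06 (3 arrays against 3, adjusted p = 0.00027) and AT5G07340 at -0.36 ± 0.08 (0.027; up to 0.11 without any 1 SA array of the double or brca2a triple, SA replicates 1 or 2); 2 of the 3 passed adjusted over the list alone. The cold and abscisic acid list was higher (adjusted p = 0.035; adjusted p = 0.40 with an estimated correlation), with COR15B at 0.90 ± 0.11 (0.00069) and COR15A at 1.5 ± 0.41 (0.078), 2 of 3 adjusted over the list alone. That call ended without double, water replicate 2 (adjusted p = 0.055), without double, water replicate 3 (0.053), without brca2a triple, water replicate 2 (0.051) and without brca2a triple, SA replicate 2 (0.24). The anthocyanin list was higher too (adjusted p = 0.014; adjusted p = 0.26 with an estimated correlation; 0.085 without brca2a triple, SA replicate 2). None of its 3 measured genes passed over all probe sets, among them the dihydroflavonol reductase gene DFR (0.69 ± 0.22, adjusted p = 0.15), and all 3 did adjusted over the list alone. AER had 0.38 ± 0.08 (adjusted p = 0.02; up to 0.082 without any 1 SA array of the double or brca2a triple, SA replicates 2 or 3). The other 5 testable lists had adjusted p between 0.33 and 0.88. Of all probe sets 970 differed after SA, 318 higher and 652 lower, including 465 named loci, and 252 differed at least 2-fold; without double, water replicate 2, which enters only through the shared spread, the count was 2028.

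The sixth comparison asked what SA did in npr1 sni1 ssn2. CCL rose 19.9-fold (4.32 ± 0.06 on the log2 scale, 2 arrays against 3, adjusted p = 9e-07), AT3G62550 by 4.13 ± 0.07 (1.7e-06), the cold- and clock-regulated gene COR27 by 3.84 ± 0.10 (4.8e-06), AT4G30660 by 3.23 ± 0.11 (1.4e-05) and COR15A by 3.02 ± 0.11 (1.6e-05). AT4G30650, AT4G05150 and AT4G16146 rose by 3.01, 2.73 and 2.72. AT1G55960 fell 24.1-fold (-4.59 ± 0.07, adjusted p = 9e-07), and AT2G41250 had -3.61 ± 0.08 (3.3e-06), AT5G12110 -3.55 ± 0.06 (1.7e-06), AT5G15950 -3.53 ± 0.13 (1.6e-05) and AT4G27280 -3.44 ± 0.08 (3.6e-06). AT5G54130 had -3.20 on 1 probe set and -2.85 on another, and AT3G09440 and AT5G42760 had -3.17 and -3.16. The clock gene GI (GIGANTEA) fell by 2.53 ± 0.14 (7.9e-05). SA changed 7558 probe sets, 4269 higher and 3289 lower (3837 and 3880 after median centring), including 3991 named loci; 1025 changed at least 2-fold.

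All 3 cold and abscisic acid genes rose in the ssn2 triple, COR15A as given above, COR15B by 1.96 ± 0.12 (2 arrays against 3, adjusted p = 1e-04) and COR47 by 0.53 ± 0.05 (0.00042), also adjusted over the list alone. The list passed (adjusted p = 0.0023) but with an estimated correlation it had adjusted p = 0.56. The other 7 testable lists did not pass, with adjusted p between 0.33 and 0.58. Their members past the threshold included PORB, a chlorophyll synthesis gene (0.97 ± 0.08, adjusted p = 0.00039), DFR (0.89 ± 0.07, 0.00031), UGT73B5 (0.66 ± 0.08, 0.0016) and the thionin gene THI2.1 (0.32 ± 0.06, 0.0056). BIK1, a receptor-like cytoplasmic kinase gene of immunity, rose by 0.67 ± 0.06 (adjusted p = 5e-04), and the root marker PYK10 fell by 0.47 ± 0.05 (0.00085). ATERDJ3B (0.26, adjusted p = 0.014), AT5G07340 (0.22, 0.025), UGT76B1 (0.30, 0.0094), AER (0.44, 0.039), GSTU25 (0.27, 0.034) and LHCB4.1 (0.26, 0.047) lost their calls without single arrays; without an SA replicate the 1 SA array left is assumed to vary like the water arrays. Their adjusted p rose to 0.054 without water replicate 1 and 0.052 without SA replicate 2 for ATERDJ3B, to 0.1 without water replicates 1 or 2 or either SA replicate for AT5G07340, to 0.054 without SA replicate 2 for UGT76B1, to 0.18 without water replicate 2 or either SA replicate for AER, to 0.11 without any water replicate or SA replicate 2 for GSTU25, and to 0.22 without water replicates 1 or 2 or either SA replicate for LHCB4.1.

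Set side by side without a test, because the tables were normalized separately, the SA effect on GRX480 was 2.46 ± 0.17 in the double and 0.11 ± 0.12 in the ssn2 triple, and that on WRKY53 was 1.93 ± 0.09 and 0.17 ± 0.08. Neither passed in the ssn2 triple (adjusted p = 0.59 and 0.16). CML38 had 2.89 ± 0.19 and -0.06 ± 0.05, STZ 2.19 ± 0.17 and -2.70 ± 0.06, and AT5G52760 3.40 ± 0.15 and 0.46 ± 0.08. AT5G55450 had 3.16 ± 0.22 and 1.69 ± 0.06, AT5G03350 2.83 ± 0.09 and 1.39 ± 0.06, and AT5G52750 2.74 ± 0.16 and 0.77 ± 0.11. COR27 had 0.21 ± 0.06 in the double and 3.84 ± 0.10 in the ssn2 triple. Over the held-out probe sets described for the interaction, the median SA effect in the ssn2 triple was 0.191, 0.368 and 0.166. Across all probe sets the SA effects of the ssn2 triple correlated with those of the double at r = 0.258 (rho = 0.243) and with those of the brca2a triple at r = 0.471 (rho = 0.45). The former was 0.398 without double, water replicate 2 and 0.154 and 0.164 without its replicates 1 and 3. Of the 1123 probe sets higher in the double, 517 were also higher in the ssn2 triple, where independent lists would share 211. Of the 577 lower ones 229 were also lower, against 83.4. The excess was smaller among the 11373 brighter probe sets, with 412 higher in both against 231 and 211 lower in both against 120.

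Of the 21 lists fixed in advance, 13 had fewer than 3 genes with a one-gene probe set and were not tested. The DNA damage response, camalexin and indole glucosinolate, flower and seed marker lists and the list of mutated genes had none. The SA synthesis and signalling list had SAG101 and UGT76B1, and the latter had 0.89 ± 0.28 in the double (3 arrays against 3, adjusted p = 0.093). The heat shock list had AT1G53540 and ATHSP22.0, whose SA effects lay between -0.09 and 0.07 in the 3 genotypes, and the senescence list SAG29 and WRKY6, of which neither passed in any of the 6 comparisons. The immunity receptor list (BIK1), the clock list (GI) and the root list (PYK10) had 1 gene each, and these 3 genes passed only for SA in the ssn2 triple. Their log2 fold changes for SA in the double were 0.18, -0.25 and 0.10 (adjusted p = 0.76, 0.54 and 0.85). The smallest p among the tested recombination and repair genes in the double belonged to RAD51B, at -0.10 ± 0.06 (adjusted p = 0.45).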

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

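The explanations weighed in the next 3 paragraphs, their tests and the tests of the 25S ribosomal RNA probe set were chosen after the results were seen, while the counts of other splits of the arrays were planned.

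Water replicate 2 of the double stood apart from replicates 1 and 3 of its group. A swap with an SA array of the double is argued against, because each of those arrays correlated better with its own group than with water replicates 1 and 3, by at least 0.0148. An SA array of the brca2a triple under its label is argued against too, since its highest correlation with those arrays minus the lowest among them was -0.00394, and so is RNA degradation, with 0 of 4 control ratios of 3-prime to 5-prime signal outside the range of the other 11 arrays. A harvest in the dark or at another hour stays possible, but these values cannot decide it. On this array 5 genes that rise in darkness (AT3G15450, AT4G27450, AKINBETA1, MCCA and IVD) exceeded the mean of replicates 1 and 3 by a median of 1.33 (log2). The daylight gene HYH had -0.83, though COR27 and AT4G33980 had -0.18 and 0.01. AT1G55960, a dark candidate dropped after its ssn2 value was seen, had -1.69 (median 1.27 over 8 genes with it and 2 other dropped candidates). All 5 genes were also higher after SA in the brca2a triple (median 0.776, camera adjusted p = 0.0018, 0.55 with an estimated correlation). None of the 5 passed limma over all probe sets there. A higher level of these genes was therefore not limited to this array. Whether those SA arrays differed in light or hour was not tested, so this does not decide its cause. Water replicate 2 also correlated better with the SA arrays of the brca2a triple (0.987 to 0.990) than with its own group (0.981 and 0.980). A sample from outside the 12 arrays stays open, as does a difference in ribosomal RNA content, since the 25S ribosomal RNA probe set was highest on this array (11.14; 9.76 to 10.83 on the others), and no biological explanation was tested.

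SA changed more probe sets in the ssn2 triple (7558) than in the double (1700) or the brca2a triple (1057). Part of this gap depended on 1 array, as the latter 2 counts were 4464 and 3495 without double, water replicate 2. A smaller spread between the ssn2 arrays does not account for the whole gap, because the number that changed at least 2-fold with no test was 2.96 times that of the double (1025 against 346). RNA degradation is argued against, as 0 of 4 control ratios of 3-prime to 5-prime signal differed by more than 0.5 between SA and water (GAPDH differed by 0.12, exact p = 0.1, the smallest possible), but the 25S ribosomal RNA probe set was higher by 0.99 after SA, so ribosomal RNA content stays open. Harvest in other light or at another hour is a candidate explanation: the daylight genes AT4G33980 and HYH, not among those named for the largest changes, had 2.33 and -2.59, a median size of 2.46 against 0.24 in random lists of 2 genes (percentile 100 of 10000 lists), though AT4G33980 also responds to cold and the daylight list of 8, which went both ways, had adjusted p = 0.2. That test took sizes without direction, and the 2 genes went opposite ways, so it cannot point to light or hour in particular. The cold and abscisic acid list was higher too (camera adjusted p = 0.0023, 0.56 with an estimated correlation), and whether cold played a part was not tested. An effect of ssn2 itself stays open and untested, since no array of another genotype was normalized with these.

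Rapid stress genes rose with SA in the double and not in the brca2a triple. Over 27 such genes, 26 rose in the double (median 1.53; adjusted p = 7.2e-48, 0.00037 with an estimated correlation) and 2 in the brca2a triple (median -0.195, downward, adjusted p = 0.06; 0.00083 to 0.049 without single arrays, but 0.87 with a median of -0.00328 over the 14 members not seen before), and for 21 the SA effect differed (26 adjusted over the list alone; median -1.73, adjusted p = 1.3e-47, 0.00038 with an estimated correlation). The values over 27 genes include members whose values had been seen when the list was written, so they partly restate that choice. The 14 members not seen before rose by a median of 1.08 in the double, 13 of them past the threshold. Their median difference was -0.89 (camera, estimated-correlation adjusted p = 0.00039), so the pattern may extend beyond the genes that prompted it. Handling of 1 or 2 of the 3 double SA harvests is argued against, because in these 14 members 3 of 3 double SA arrays had a mean (7.26 to 7.32) above each of the other 9 arrays (6.17 to 6.38). Handling that was alike at all 3 of these harvests stays open beside an effect of brca2a.

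Counts were also made with the arrays split otherwise between the groups. For the difference in SA effect between the genotypes (442 probe sets), 8 of 100 splits, the real one included, had as many calls, and the highest other had 612, so chance is not excluded by this count. The 7 other splits with as many calls all kept the SA arrays divided by genotype, as 12 of the 100 did, and exchanged only water arrays; among splits that mixed the SA arrays the highest count was 1. The other comparisons have 10 splits each, too few for a share under 0.05; in each, 1 of 10 (the real one) reached the real count. The real counts and the highest others were 1700 and 0 (SA in the double), 1057 and 56 (SA in the brca2a triple), 17 and 4 (genotypes in water) and 970 and 0 (genotypes after SA).

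The 442 differences in SA effect included AT4G17470 (2.0), ARR15 (1.80), JAL23 (1.60), AT1G30250 (1.07), AT2G43530 (1.05), AT2G43550 (1.01), AT5G44050 (0.96) and AT5G47330 (0.92) in one direction. In the other they included AT4G29780 (-3.38), CML38 (-3.26), AT5G52760 (-3.20), AT3G01830 (-2.89), STZ (-2.71), AT2G27080 (-2.61), AT4G27654 (-2.60), AT1G15010 (-2.40), GRX480 (-2.35), WRKY53 (-1.92) and ATERDJ3B (-0.61). The 25S ribosomal RNA control probe set was higher after SA than in water by 0.48 in the brca2a triple and 0.99 in the ssn2 triple, with every SA array above every water array, and had -0.35 in the double (log2 as deposited; exact permutation p = 0.1, 0.1 and 0.3, where 0.1 is the smallest these arrays allow).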

How the results depend on the processing

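Array weights, and, for the added lists and families, leaving out arrays and returning dropped candidates (given with them), were chosen after the results were seen; the other alternatives were planned. Precision is limited by the number of arrays; where a count moved, the cause was not tested. For SA in the double (1700) counts were 939 with its groups alone, 309 at least 2-fold, 4523 with array weights, and between 1090 (without double, SA replicate 1) and 4464 (without double, water replicate 2). For SA in the brca2a triple (1057) they were 2599 with its groups alone, where water replicate 2 of the double no longer enters the spread, 1970 at adjusted p under 0.1, 75 at least 2-fold, 2625 with array weights, and 379 (without brca2a triple, SA replicate 3) to 3495 (without double, water replicate 2). For the difference in SA effect (442) they were 753 at 0.1, 195 at least 2-fold, 826 with array weights, and 329 (without double, SA replicate 3) to 1065 (without double, water replicate 2). For the genotypes in water (17) they were 2 with groups alone, 44 at 0.1, 2 at least 2-fold, 11 with the series value table, 27 with single-gene probe sets, 27 with array weights, and 1 (without double, water replicate 3) to 107 (without double, water replicate 2). For the genotypes after SA (970) they were 2040 with groups alone, 252 at least 2-fold, 2326 with array weights, and 662 (without brca2a triple, SA replicate 3) to 2028 (without double, water replicate 2). For SA in the ssn2 triple (7558) they were 1025 at least 2-fold and 5899 (without water replicate 1) to 7091 (without water replicate 3). With the replicate number as a block the counts were 1568, 1016, 438, 3, 932 and 7001, in this order, and the numbers did not pair arrays: 1 of 18 same-number pairs had r over 0.1 (range -0.327 to 0.157). In water the block ended the calls of AT5G03350 (adjusted p = 0.08), AT3G56480 (0.057), AT1G77600 (0.057), AT2G30620 (0.096) and AT4G30310 (0.081), and not that of COR15B. Calls of gene lists (8) were 1 with an estimated correlation, 18 with fry, 8 with the block, and 7 (without double, water replicate 2) to 9 (without brca2a triple, SA replicate 2). Of the named genes past the threshold, 19 of 25 (SA in the double), 7 of 19 (SA in the brca2a triple), 15 of 19 (difference), 0 of 6 (water), 21 of 23 (after SA) and 25 of 31 (SA in the ssn2 triple) kept an adjusted p under 0.05 in every alternative run on single genes, which a 2-fold minimum was not, and none reversed. Alternatives for the difference between the ssn2 triple and the double, and for the genes mutated here (offset 1), were not run, as neither was tested.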

Other observations

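The gene families, the further lists with their tests, and the correlation of water replicate 2 with SA effects were chosen after the results were seen. Among 9 measured xyloglucan endotransglucosylase genes, enzymes that remodel the cell wall, XTH18 rose with SA in the double by 2.42 ± 0.16 (3 arrays against 3, adjusted p = 8.7e-06), XTH33 by 0.90 ± 0.12 (0.00076), XTH19 by 0.65 ± 0.11 (0.0044) and XTH16 by 0.55 ± 0.08 (0.0016). In the brca2a triple XTH33 rose by 0.90 ± 0.12 (adjusted p = 0.005) and XTH16 by 0.46 ± 0.08 (0.013), while XTH18 and XTH19 had 0.16 and -0.29 (0.63 and 0.17). The SA effects on XTH18 and XTH19 differed between the genotypes by -2.26 (adjusted p = 0.00051) and -0.94 (0.01). Of the ubiquitin ligase genes, PUB23, PUB24 and PUB22 rose in the double by 2.06, 0.72 and 0.60, and the SA effect differed for PUB23 (-2.40, adjusted p = 0.00019) and PUB22 (-0.75, 0.013). WRKY22 rose by 1.07 ± 0.07 (7.3e-06) and CML37 by 0.56 ± 0.04 (1.6e-05) in the double, with differences of -0.89 (0.00085) and -0.60 (0.00047).

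In the ssn2 triple SA raised 5 of 8 measured autophagy genes (7 adjusted over the family alone), among them ATG8E and ATG8F, both by 0.96 ± 0.05 (2 arrays against 3, adjusted p = 4.2e-05 and 5.1e-05), and ATG8D by 0.56 ± 0.10 (0.0079). CML41 rose by 1.80 ± 0.07 (adjusted p = 1.7e-05), and XTH32, CML23 and PUB26 had -2.13, -1.67 and -1.29 (9.3e-05, 3.7e-05 and 7.2e-05). Dark genes went both ways: of the 7 in the list 5 rose, among them AKINBETA1 by 1.67 ± 0.05 (9.1e-06), and 2 were lower without passing, while of 3 candidates left out of the list AT1G55960 (-4.59) and AT1G26800 (-0.50) fell and AT2G05540 rose (0.35).

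Of 40 families, CML (calmodulin-like; adjusted p = 0.00024) and WRKY (0.0051) were higher with SA in the double, CML (0.00015) and PUB (0.0092) had a lower SA effect in the brca2a triple, and CML (1.1e-06), PUB (0.00037) and WRKY (0.0076) were lower in it after SA. These calls held without each array, and so did that of ATG, higher with SA in the ssn2 triple (0.004). With an estimated correlation their adjusted p was 0.16, 0.16, 0.15, 0.15, 0.06, 0.06, 0.19 and 0.84. The CML, PUB and WRKY families had 7, 9 and 6 loci here. They hold CML38, PUB23 and WRKY53, named above from the same data, so their calls partly restate those genes. The other calls ended without single arrays. For SA in the double, XTH (0.00024), PUB and the plastid-encoded genes (0.0051 each), upward, and PDF (defensins; 0.041), downward, had 0.2, 0.16, 0.84 and 0.26 with an estimated correlation and 0.054, 0.36, 0.29 and 0.13 without double, water replicate 2. Without double, SA replicate 2 the plastid-encoded genes had 0.26 and PDF 0.1, and PDF also lost its call without double, water replicate 1 (0.065) and brca2a triple, water replicates 1 and 2 (0.056 and 0.052). Of the differences in SA effect, WRKY (0.036; 0.36 with an estimated correlation) had 0.11 and 0.067 without double, water replicates 1 and 3, and 0.078 and 0.055 without brca2a triple, water replicate 1 and SA replicate 3. RPS (ribosomal proteins, some of them plastid-encoded; 0.043, 0.62 with an estimated correlation) had 0.28 and 0.06 without double, water replicates 2 and 3, 0.18 without double, SA replicate 2, and 0.084, 0.16 and 0.18 without brca2a triple, water replicate 1 and SA replicates 1 and 3. The plastid-encoded genes (0.0045; 0.7 with an estimated correlation) had 0.44 without brca2a triple, SA replicate 3. After SA, RPS (0.026; 0.63 with an estimated correlation) had 0.056, 0.26, 0.17 and 0.21 without double, water replicate 2 and SA replicate 2 and brca2a triple, SA replicates 1 and 3, and the plastid-encoded genes (1.7e-07; 0.63 with an estimated correlation) had 0.07 without brca2a triple, SA replicate 3. In the ssn2 triple the plastid-encoded genes (0.004; 0.84 with an estimated correlation) had 0.27 without SA replicate 2, where the 1 SA array left is assumed to vary like the water arrays. With all arrays no family passed camera for SA in the brca2a triple or for the genotypes in water, where 8 and 4 had an unadjusted p under 0.05, and fry called 4 and 1. For SA in the brca2a triple calls appeared without single arrays of that genotype: SEC (0.077), upward, had 0.014, 0.043 and 0.043 without water replicate 1 and SA replicates 1 and 3, and RPS (0.36) and the plastid-encoded genes (0.46), downward, had 0.038 and 4.5e-05 without SA replicate 2. Elsewhere calls of BZIP, XTH, RPL, TBL, PDF and RPS appeared in the same way (0.00045 to 0.049).

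Iron deficiency genes fell with SA in the double and the brca2a triple. Of 6 measured, 4 fell in each (adjusted p of the list = 0.0048 and 0.00041; 0.041 and 0.031 with an estimated correlation; 0.004 and 0.00052, and 0.051 and 0.039 with an estimated correlation, when the dropped glucosinolate list and dark candidates were put back, so the estimated-correlation call in the double ended): besides AT1G47400 and BHLH101, PYE (-0.36 and -0.65) and AT5G05250 (-0.76 and -1.11). In the ssn2 triple 4 rose (BHLH101 by 1.32, AT5G05250 by 1.16, AT1G47400 by 0.84, AT3G07720 by 0.44) and PYE fell by 0.41 (list adjusted p = 0.045, 0.16 with an estimated correlation and 0.085 when the dropped glucosinolate list and dark candidates were put back; 0.051 without ssn2 triple, water replicate 1, and 0.1 without SA replicate 1, where the 1 SA array left is assumed to vary like the water arrays). Whether the iron deficiency genes respond as a group stays open: 4 of the 6 had prompted the list, and the other 2, AT1G74770 and AT3G07720, went opposite ways (-0.13 and 0.15 in the double, 0.06 and -0.06 in the brca2a triple), so their median of 0.01 decides nothing.

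With all arrays the daylight list did not pass in any comparison (adjusted p between 0.082 and 0.99), though without double, water replicate 2 it was lower for SA in the double (0.0051) and the brca2a triple (0.0044) and in the brca2a triple in water (0.022); for SA in the ssn2 triple, where 3 of its 8 genes rose and 5 fell, it had adjusted p = 0.2. The dark list of 7 had adjusted p = 0.028 (SA in the double), 0.00013 (brca2a triple) and 0.0053 (ssn2 triple), upward, and 0.43, 0.27 and 0.12 with an estimated correlation. Its 3 dropped candidates, of which AT1G55960 was dropped after its fall in the ssn2 triple had been seen, were put back for a further test. With all 10 the values were 0.064, 0.00041 and 0.23 (0.43, 0.29 and 0.38 with an estimated correlation). So no rise of dark genes is claimed for the double or the ssn2 triple, and the call in the brca2a triple did not hold with an estimated correlation. The 5 members not seen before had 0.066, 0.0018 and 0.0022 (0.46, 0.55 and 0.16 with an estimated correlation). In the double the list of 7 had 0.24 and 0.33 without water replicates 1 and 3. No single gene of the 7 passed limma over all probe sets in the double or the brca2a triple (0 and 6 adjusted over the list alone). For the genotypes in water the dark list was lower in the brca2a triple (0.046, 0.68 with an estimated correlation). It had 0.13 over the 5 members not seen before and 0.0034 over all 10 (0.39 with an estimated correlation). But without double, water replicate 2 the direction of the list of 7 reversed (upward, 0.022). That list had 0.19 and 0.2 without brca2a triple, water replicates 1 and 3 and 0.053 to 0.056 without any 1 SA array. Rapid stress genes were lower in the brca2a triple after SA (25 of 27, adjusted p = 6.7e-59, 0.00017 with an estimated correlation), which includes the genes that prompted the list. Of the 14 members not seen before 12 were lower (median -0.948, camera adjusted p = 0.00015 with an estimated correlation). In the ssn2 triple 3 of the 27 rose and 10 fell with SA (adjusted p = 0.0032, 0.12 with an estimated correlation). Of the 14 members not seen before 2 rose and 3 fell there (0.052). A dropped list of 4 glucosinolate genes, 3 of them seen before, had adjusted p = 0.004 (lower, SA in the double), 0.074 (SA in the brca2a triple), 0.00035 (higher, difference in SA effect), 0.00022 and 7.7e-09 (higher in the brca2a triple in water and after SA) and 0.85 (SA in the ssn2 triple), and 0.098, 0.35, 0.062, 0.092, 0.0067 and 0.86 with an estimated correlation. Across probe sets, water replicate 2 minus replicate 3 of the double correlated with SA effects from arrays it did not share at r = 0.487 (double), 0.612 (brca2a triple) and 0.478 (ssn2 triple).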
